A study of Homo sapiens and Mus musculus with 16 samples.

How the data were processed

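Total RNA was extracted with Qiagen RNeasy kits, depleted of ribosomal RNA and sequenced, per the labels' protocols. The series holds 16 libraries: 5 human alveolar soft part sarcomas (ASPS), 3 human quadriceps muscle samples, 5 mouse tumours driven by the ASPSCR1-TFE3 fusion and 3 mouse quadriceps samples. Groups and replicate numbers were taken from the sample titles. Novoalign 2.08.01 and the genome builds hg19 and mm10 are named in the submitters' processing notes. The program that counted reads per gene, its annotation, its use of strand and any filter on genes are not given in the sources used here.

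Each species had one table with a row per Ensembl gene and 3 columns per library. The deposited counts are whole numbers of reads per gene, and the authors did not normalise them, per the file headers and as their totals differ between libraries. There were 17765 human and 16184 mouse genes, and the lowest total of a gene over its 8 libraries was 10 in human and 12 in mouse. The deposited normalised values are on a log2 scale, per the file headers and the values, with a floor at 2.50 in human and 2.02 in mouse for a count of 0. How the authors scaled these log2 values is not given in the sources used here. The deposited FPKM values (fragments per kilobase of gene model and 1e6 reads) were checked on 2 libraries per species, where the count to FPKM ratio differed between libraries by one constant over all genes, with a relative SD of 1.43e-09 in human and 3.85e-09 in mouse. The gene model lengths behind the deposited FPKM values are not given in the sources used here, and a length in kilobases was worked out from the count and the FPKM of each gene for a check of length. Every column of the tables belonged to one of the 16 libraries.

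Tests were run on the counts with edgeR 4.0.16 under R 4.3.3. Genes were kept by edgeR's filterByExpr, libraries were scaled by TMM, and each species was fitted alone with the quasi-likelihood test of tumour against muscle. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a species, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken as the fold change divided by the square root of its F statistic. CPM in the text (counts per 1e6 reads) were scaled by TMM, so that CPM of one library need not sum to 1e6. TMM factors were 1.40 to 1.68 in human tumours and 0.435 to 0.574 in human muscle. They lower tumour levels against muscle, so falls of modest size depend on this scaling. For some genes called lower, among them SLC16A1, MPC2, NBR1 and ATF4, mean deposited FPKM, which carry no TMM factor, were not lower in tumours. The median log2 change of all tested genes was 0.13 in human and 0.12 in mouse, and over the scalings tried in human it lay between 0.09 and 0.18. The labels do not say that the samples of a group came from separate donors or animals. The p-values set each difference against the spread between these samples only, and may be too small if samples share a donor or animal.

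Human gene symbols were matched by Ensembl ID to a GRCh38 annotation, which gives a symbol to 16736 of the 17765 IDs. Of these, 11 share a symbol with another ID and were not named. Chromosomes, exon overlaps and distances between neighbouring genes were taken from that build, which is not the hg19 build of the counts, so overlaps are approximate. In that annotation 4254 genes of the table share at least 50 exon bases with another gene of the table, so the split of reads between them depends on counting rules that are not given. The annotation used here covers human genes, so matching of the 16184 mouse IDs to symbols was not tried and mouse gene names were not used here. The design set out before the data were examined also held a test of the species difference, the overlap and correlation of changes between species, the similarity of single mouse and human tumours, and gene lists in mouse. All of these need symbols matched between species and are not analysed here. Values of 36 human genes that carry information on a donor are not reported. Some single genes named by the rule below, and 2 gene lists chosen after the values were seen, are not reported here.

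Before the data were examined, 29 gene lists with 475 entries were written, of which 421 entries were in the human table, and lists with fewer than 3 tested members were not tested. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, with a preset correlation of 0.01 between genes and two-sided p-values adjusted over the 25 lists tested. The test was repeated with a correlation estimated from the data. Counts of called members are given over all genes tested and adjusted over the list alone.

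The genes named in the text follow a rule fixed before the data were examined. They are 12 genes tied to ASPS, the 8 largest changes in each direction with at least 20 CPM in the higher group and no overlap between groups, and up to 3 called members of each list in the direction of most called members with 1 in the other direction. Of the list members named by the rule, the text gives those with the smallest adjusted p. Where a group had no read of a gene, the fold is a lower bound against a floor of 3 counts over the group. Where a group had 1 to 3 reads, the ratio is given with a 95% Poisson interval of the low count. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

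The fits were checked on simulated negative binomial counts with the observed mean shares, dispersions and library totals, equal means in tumour and muscle, and known changes added to chosen genes. In the human simulation over 14918 genes, 4.21% of 95 genes changed 2-fold and 60% of 100 genes changed 4-fold were called, and 8.57% of the calls were false. In the mouse simulation over 14494 genes, 21.6% of 97 genes changed 2-fold and 75% of 100 genes changed 4-fold were called, and 3.03% of the calls were false. The list test called the changed list and 0 of the others in both simulations. Few genes were changed, and no gene took a large share of the counts in muscle alone. The simulations therefore do not give the recovery for data in which 51.0% of human genes tested were called. Nor do they check TMM on muscle libraries dominated by a few genes.

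Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, TMM without the muscle, respiration and glycolysis lists in human, no filter on low counts, a filter of at least 5 CPM in 3 libraries, a 2-fold minimum, the replicate number as a block, each library left out in turn, and for lists the estimated correlation and fry. Summing the closest libraries, TMM without the 50 genes most abundant in muscle and limma on the deposited log2 values were chosen after seeing the data. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.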

Results

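The series compares ASPS, a sarcoma defined by a fusion of ASPSCR1 to the transcription factor gene TFE3, with tumours that the same fusion induces in mice, and uses skeletal muscle of each species as the common reference. Counts per gene were read from 5 tumours and 3 muscle samples of each species. Total counts, with M for 1e6 reads, were 4.64 to 6.58 M per library in human tumours (mean 5.86 ± 0.728, SD, n = 5) and 9.34 to 13.4 M in human muscle (mean 10.8 ± 2.27, SD, n = 3). In mouse they were 9.45 to 15.002 M in tumours (mean 12.6 ± 2.00, SD, n = 5) and 9.90 to 10.7 M in muscle (mean 10.3 ± 0.389, SD, n = 3).

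Muscle libraries were dominated by a few genes. The most abundant gene took 43.8% ± 4.59 of the counts in human muscle (SD, n = 3) and 1.68% ± 0.588 in human tumours (SD, n = 5). In mouse it took 24.0% ± 4.36 of muscle counts (SD, n = 3) and 2.24% ± 0.609 of tumour counts (SD, n = 5). In human muscle that gene was TTN (ENSG00000155657), which encodes the giant sarcomere protein titin. Human tumours correlated with each other at a Spearman rho of 0.896 to 0.986 across genes, human muscle samples at 0.960 to 0.985, and tumours with muscle at 0.764 to 0.793. In mouse the ranges were 0.937 to 0.973 within tumours, 0.978 to 0.990 within muscle and 0.676 to 0.717 between the tissues. Human tumours 2 and 3, human muscle 1 and 3 and mouse muscle 1 and 3 were closest, with a mean chi-square per gene of 5.77, 5.72 and 4.27. The medians were 1.20, 0.699 and 0.855. Sampling noise alone gives a mean of 1 and a median well below 1. These values do not exclude that a pair came from one donor or animal, and each library was counted as a sample of its own by its title.

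**Figure D1:**
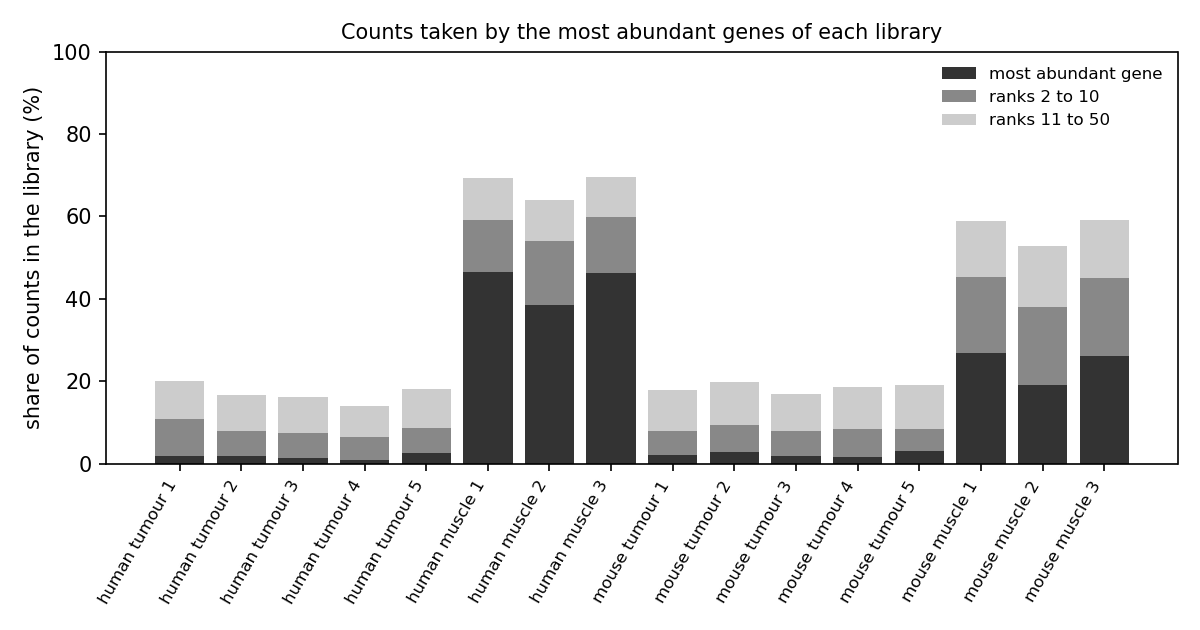
Each bar is a library and its height the percentage of that library's counts taken by its 50 most abundant genes, split into the most abundant gene, ranks 2 to 10 and ranks 11 to 50. The most abundant gene takes 38.5% to 46.6% of the counts in human muscle and 0.870% to 2.47% in human tumours.

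The human comparison asks how ASPS differs from skeletal muscle. Genes of the lysosome and genes tied to TFE3 family factors were higher in the tumours, and contractile genes of muscle were far lower. GPNMB (ENSG00000136235), a glycoprotein of lysosomes and melanosomes, had the highest mean level of all genes in the tumours at 10790 ± 4574 CPM (SD, n = 5) against 170 ± 30.9 CPM in muscle (SD, n = 3). Of 32 lysosomal genes tested 28 rose. All 29 contractile genes tested fell. The tumours also carried more transcript of macrophage markers, of genes of dividing cells and of genes for melanosome-type vesicle transport. After scaling between libraries, they carried less of nuclear genes for the respiratory chain. With an estimated correlation none of these lists passed, neither the lysosome, TFE3 family and contractile lists (camera, adjusted p = 0.257, 0.333 and 0.257) nor the macrophage, dividing cell, vesicle and respiration lists (camera, adjusted p = 0.469, 0.432, 0.0731 and 0.519). By edgeR's quasi-likelihood test, 7794 of 15277 genes tested (51.0%) differed at an adjusted p under 0.05, 4244 higher and 3550 lower in tumours. Among these, 3410 were at least 2-fold higher and 2351 at least 2-fold lower, and 515 and 393 at least 16-fold. Every tumour lay on one side of every muscle sample for 7755 genes, of which 7064 were called, where chance separates 3.57% of genes. With the closest libraries summed, an alternative chosen after seeing the data, 5095 genes were called.

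The 12 genes named in advance for their ties to ASPS went different ways. CTSK (ENSG00000143387), the protease cathepsin K, reached 2107 ± 308 CPM in tumours (SD, n = 5) and 42.2 ± 6.76 CPM in muscle (SD, n = 3), a log2 change of 5.64 (SE 0.32, edgeR, adjusted p = 3.24e-06). GPNMB rose by 5.99 on the log2 scale (SE 0.63, edgeR, adjusted p = 8.73e-05). UPP1 (ENSG00000183696), the uridine-cleaving enzyme uridine phosphorylase 1, rose by 5.27 (SE 0.59, edgeR, adjusted p = 1.26e-04) to 555 ± 296 CPM (SD, n = 5). VEGFA (ENSG00000112715), the main growth factor of blood vessels, rose by 1.78 (SE 0.42, edgeR, adjusted p = 0.00713). PGF (ENSG00000119630), a related factor, had a log2 change of 1.20 that missed the threshold (SE 0.51, edgeR, adjusted p = 0.0770) and passed it without tumour 4 (edgeR, adjusted p = 0.0487). The fusion partners TFE3 (ENSG00000068323, chromosome X) and ASPSCR1 (ENSG00000169696, chromosome 17) had log2 changes of 0.53 (SE 0.27, edgeR, adjusted p = 0.128) and -0.17 (SE 0.22, edgeR, adjusted p = 0.542) as whole genes. Counts per gene do not tell fused from normal transcripts. TFE3 also had counts close to those of its neighbour GRIPAP1, so the split of reads between them may be uncertain. MET (ENSG00000105976), the receptor of hepatocyte growth factor, was at 131 ± 29.8 CPM in tumours (SD, n = 5) and 119 ± 7.44 CPM in muscle (SD, n = 3), a log2 change of 0.14 (SE 0.21, edgeR, adjusted p = 0.601). LDHB (ENSG00000111716), a lactate dehydrogenase subunit, rose by 1.48 (SE 0.33, edgeR, adjusted p = 0.00523). Its partner LDHA (ENSG00000134333) fell by 2.29 (SE 0.37, edgeR, adjusted p = 0.00103). The lactate transporters SLC16A1 (ENSG00000155380) and SLC16A3 (ENSG00000141526) fell by 1.25 (SE 0.30, edgeR, adjusted p = 0.00730) and 2.27 (SE 0.37, edgeR, adjusted p = 0.00103). SLC16A1 was at 109 CPM in muscle 2, below tumour 2 at 115 CPM, and at 271 and 241 CPM in muscle 1 and 3. With the closest libraries summed, the calls of LDHB and SLC16A1 were lost (edgeR, adjusted p = 0.0527 and 0.0532), and that of SLC16A1 also with the replicate block (edgeR, adjusted p = 0.0536).

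**Figure D2:**
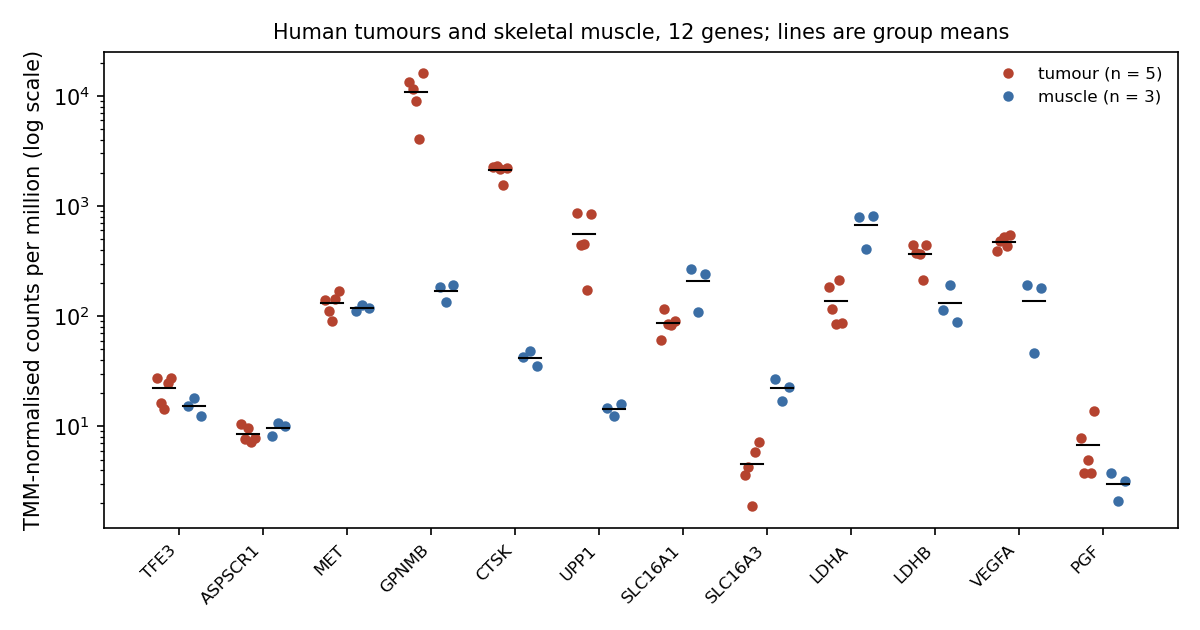
Points are TMM-normalised counts per M of single human libraries on a log axis for the 12 genes, 5 tumours beside 3 muscle samples, and lines are group means. GPNMB, CTSK and UPP1 lie at 4077 to 16086, 1564 to 2312 and 173 to 857 CPM in tumours, above every muscle sample, while TFE3, ASPSCR1, MET and SLC16A1 overlap between the groups.

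The list of TFE3 family targets and ASPS markers held 17 tested genes, of which 12 rose and 1 fell, with the same counts adjusted over the list alone and a median log2 change of 1.75. The list passed the test (camera, adjusted p = 4.68e-05) and did not with an estimated correlation (camera, adjusted p = 0.333). HIF1A, the oxygen-regulated subunit of hypoxia-inducible factor 1, rose by 4.05 (SE 0.22, edgeR, adjusted p = 2.86e-06). Its level was 56.1 ± 0.802 CPM in muscle (SD, n = 3) and 931 ± 100 CPM in tumours (SD, n = 5). RRAGC, a GTPase that recruits mTORC1 to the lysosome, rose by 3.19 (SE 0.28, edgeR, adjusted p = 3.31e-05). The member that fell was SLC16A1.

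Lysosomal genes rose as a group. Of 32 tested, 28 rose and 0 fell, with 28 also adjusted over the list alone, and the median log2 change was 2.57 (camera, adjusted p = 3.68e-11). With an estimated correlation the list was not called (camera, adjusted p = 0.257). NPC2 and NPC1, which move cholesterol out of lysosomes, rose by 3.87 (SE 0.23, edgeR, adjusted p = 3.84e-06) and 3.46 (SE 0.26, edgeR, adjusted p = 1.27e-05). OSTM1, a subunit of the lysosomal chloride transporter, rose by 2.88 (SE 0.19, edgeR, adjusted p = 7.11e-06). Macrophage markers were higher as well: 15 of 16 tested rose and 0 fell, 15 adjusted over the list alone, with a median of 1.78 (camera, adjusted p = 1.52e-04) and no call with an estimated correlation (camera, adjusted p = 0.469). CTSS and C1QC rose by 2.41 (SE 0.40, edgeR, adjusted p = 0.00109) and 2.46 (SE 0.44, edgeR, adjusted p = 0.00165). CD68 rose by 3.82 (SE 0.69, edgeR, adjusted p = 0.00172), or by 3.19 without tumour 1.

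Genes of regulated secretion and melanosome-type transport rose in 9 of 14 tested, 9 adjusted over the list alone, with 0 lower and a median of 2.38 (camera, adjusted p = 1.52e-04, and adjusted p = 0.0731 with an estimated correlation). RAB32 and MLPH, a small GTPase and the melanophilin that links such vesicles to myosin, rose by 4.49 (SE 0.22, edgeR, adjusted p = 2.19e-06) and 4.55 (SE 0.30, edgeR, adjusted p = 6.67e-06). The motor MYO5A rose by 1.49 (SE 0.15, edgeR, adjusted p = 5.57e-05). Of 19 autophagy genes 1 rose and 5 fell, with the same counts adjusted over the list alone and a median of -0.23, and the list was not called (camera, adjusted p = 0.0623). It was called lower without tumour 1 (camera, adjusted p = 0.0374) and without muscle 2 (camera, adjusted p = 0.0439). The cargo receptor NBR1 fell by 1.05 (SE 0.15, edgeR, adjusted p = 4.48e-04). GABARAPL2, which coats autophagosomes, rose by 1.71 (SE 0.32, edgeR, adjusted p = 0.00197).

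The contractile list fell throughout, 29 of 29 tested and 29 adjusted over the list alone, with a median log2 change of -9.19 (camera, adjusted p = 6.50e-21, and adjusted p = 0.257 with an estimated correlation). TNNC2, the calcium sensor of fast fibres, fell by 9.26 (SE 0.51, edgeR, adjusted p = 2.86e-06), RYR1, the calcium release channel, fell by 6.94 (SE 0.38, edgeR, adjusted p = 2.90e-06) and ATP2A1, the calcium pump of fast fibres, fell by 9.19 (SE 0.57, edgeR, adjusted p = 4.72e-06). TTN, chosen after its values were seen, took 0.727% ± 0.468 of tumour counts (SD, n = 5) and fell by 7.59 (SE 1.40, edgeR, adjusted p = 0.00191). In tumour 5, TTN and NEB, which encodes the thin-filament protein nebulin, stood at 0.816% and 1.21% of their muscle level, while the other 27 contractile genes had a median of 0.0387% and a highest value of 1.44% (PYGM). Muscle progenitor and myogenic factors fell in 7 of 10 tested and rose in 0, or fell in 7 and rose in 1 adjusted over the list alone, with a median of -2.63 (camera, adjusted p = 1.32e-04, and adjusted p = 0.0731 with an estimated correlation). MYOG, a transcription factor of muscle differentiation, fell by 7.68 (SE 0.57, edgeR, adjusted p = 1.20e-05). MEF2C, another such factor, fell by 3.88 (SE 0.21, edgeR, adjusted p = 2.59e-06).

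Nuclear genes of the respiratory chain and citric acid cycle fell in 21 of 29 tested, 21 adjusted over the list alone, and rose in 0, with a median of -0.97 (camera, adjusted p = 1.50e-05, and adjusted p = 0.519 with an estimated correlation). The list mean log2 CPM was 7.656, 6.935 and 7.622 in muscle 1, 2 and 3 and 6.226 to 6.928 in tumours, so muscle 2 lay close to the highest tumour. With the closest libraries summed the list was still called (camera, adjusted p = 7.93e-05). MDH2, mitochondrial malate dehydrogenase, fell by 1.98 (SE 0.26, edgeR, adjusted p = 3.29e-04). The complex I subunits NDUFS1 and NDUFV2 fell by 1.63 (SE 0.25, edgeR, adjusted p = 6.36e-04) and 1.64 (SE 0.25, edgeR, adjusted p = 7.00e-04). Glycolysis genes were split, 8 of 22 higher and 10 lower, or 9 and 10 adjusted over the list alone, with a median of -0.38 (camera, adjusted p = 0.368). SLC2A4, the insulin-responsive glucose transporter, fell by 5.21 (SE 0.32, edgeR, adjusted p = 4.71e-06) and the phosphofructokinase PFKM fell by 3.46 (SE 0.27, edgeR, adjusted p = 1.49e-05). The enolase ENO2 rose by 3.14 (SE 0.48, edgeR, adjusted p = 6.91e-04). Genes of lactate and pyruvate handling were 4 of 12 higher and 6 lower, the same adjusted over the list alone, with a median of -0.79 (camera, adjusted p = 0.524). MPC2, a subunit of the mitochondrial pyruvate carrier, fell by 1.16 (SE 0.16, edgeR, adjusted p = 4.63e-04). The monocarboxylate transporter SLC16A7 rose by 2.43 (SE 0.30, edgeR, adjusted p = 2.11e-04).

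Genes induced through hypoxia-inducible factor did not move as a group: 9 of 25 tested rose and 10 fell, or 10 and 10 adjusted over the list alone, with a median of 0.36 above 0 but a test direction below that of other genes (camera, adjusted p = 0.948). The prolyl hydroxylase EGLN1, which marks hypoxia-inducible factor for breakdown, fell by 2.38 (SE 0.22, edgeR, adjusted p = 4.30e-05), ANKRD37 fell by 2.95 (SE 0.30, edgeR, adjusted p = 7.15e-05). The secreted stanniocalcin STC2 rose by 3.06 (SE 0.28, edgeR, adjusted p = 3.95e-05). Of 14 cholesterol synthesis and uptake genes 4 rose and 2 fell, the same adjusted over the list alone, with a median of 0.16 (camera, adjusted p = 0.948). SQLE, squalene epoxidase, rose by 1.84 (SE 0.30, edgeR, adjusted p = 0.00110). FDFT1, squalene synthase, fell by 1.67 (SE 0.18, edgeR, adjusted p = 8.77e-05).

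Genes of dividing cells rose in 17 of 21 tested, 17 adjusted over the list alone, with 0 lower and a median of 2.09 (camera, adjusted p = 4.82e-05, and adjusted p = 0.432 with an estimated correlation). TYMS, thymidylate synthase, rose by 3.89 (SE 0.45, edgeR, adjusted p = 1.40e-04), to 7.36 ± 2.33 CPM in tumours (SD, n = 5). PCNA, the sliding clamp of DNA replication, rose by 1.49 (SE 0.19, edgeR, adjusted p = 2.69e-04). Genes of the amino acid response, among them the transcription factor gene ATF4, rose in 7 of 12 tested and fell in 1, or rose in 8 adjusted over the list alone, with a median of 1.86 (camera, adjusted p = 0.0377). That call was lost with an estimated correlation (camera, adjusted p = 0.432), without tumour 1 (camera, adjusted p = 0.0552) and without muscle 1 (camera, adjusted p = 0.0546). The amino acid transporter SLC7A5 rose by 3.53 (SE 0.37, edgeR, adjusted p = 7.96e-05), the stress factor DDIT3 by 2.25 (SE 0.27, edgeR, adjusted p = 1.98e-04). The member that fell, ATF4, fell by 1.70 (SE 0.29, edgeR, adjusted p = 0.00117). Immediate-early and heat-shock genes rose in 6 of 15 and fell in 1, the same adjusted over the list alone, with a median of 0.55 (camera, adjusted p = 0.154). EGR2 rose by 2.92 (SE 0.62, edgeR, adjusted p = 0.00405), or by 4.53 without muscle 2. HSPA1A, whose near-identical copy HSPA1B makes its counts uncertain, fell by 0.92 (SE 0.32, edgeR, adjusted p = 0.0369). Its call was lost when any of tumours 2, 4 and 5 or muscle samples 1, 2 and 3 was left out (edgeR, adjusted p = 0.0713, 0.0655, 0.0689, 0.0864, 0.0622 and 0.127).

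Secreted factors acting on blood vessels rose in 9 of 18 tested and fell in 1, or 9 and 2 adjusted over the list alone, with a median of 1.27 (camera, adjusted p = 0.106). MDK, the heparin-binding growth factor midkine, rose by 7.11 (SE 0.31, edgeR, adjusted p = 1.55e-06), from 3.16 ± 0.175 CPM in muscle (SD, n = 3) to 440 ± 93.0 CPM in tumours (SD, n = 5). ADM, the vasodilator adrenomedullin, rose by 2.34 (SE 0.40, edgeR, adjusted p = 0.00127). VEGFD fell by 3.93 (SE 0.28, edgeR, adjusted p = 9.92e-06). Endothelial markers rose in 6 of 19 tested, 6 adjusted over the list alone, and fell in 0, with a median of 0.44 (camera, adjusted p = 0.113). The list was called higher without tumour 4 (camera, adjusted p = 0.04005). KDR, the main receptor of VEGFA, rose by 3.01 (SE 0.24, edgeR, adjusted p = 1.95e-05). PLVAP, a protein of vessel fenestrae, rose by 3.35 (SE 0.50, edgeR, adjusted p = 5.88e-04). Markers of pericytes and vascular smooth muscle were 5 of 12 higher and 1 lower, the same adjusted over the list alone, with a median of 0.63 (camera, adjusted p = 0.440). NOTCH3 rose by 2.00 (SE 0.28, edgeR, adjusted p = 3.88e-04). The smooth muscle myosin MYH11 fell by 2.72 (SE 0.34, edgeR, adjusted p = 2.27e-04).

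Among markers of other cell types, fibroblast and matrix genes were 1 of 16 higher and 3 lower, the same adjusted over the list alone, with a median of 0.37 (camera, adjusted p = 0.820). PDGFRA fell by 3.19 (SE 0.21, edgeR, adjusted p = 7.02e-06). THY1 rose by 3.62 (SE 0.72, edgeR, adjusted p = 0.00286), or by 4.41 without muscle 2. Cartilage and bone genes rose in 4 of 6 tested, 5 adjusted over the list alone, and fell in 0, with a median of 3.09 (camera, adjusted p = 0.0284, and adjusted p = 0.340 with an estimated correlation). PHEX, an endopeptidase of bone cells, rose by 5.50 (SE 0.73, edgeR, adjusted p = 3.19e-04), or by 7.15 without muscle 2. ACAN, which encodes the proteoglycan aggrecan, rose by 3.17 (SE 0.72, edgeR, adjusted p = 0.00553). Fat cell markers were 1 of 8 higher and 3 lower, the same adjusted over the list alone, with a median of -1.35 (camera, adjusted p = 0.0648). The list was called lower without tumours 1, 2 or 3 or muscle 3 (camera, adjusted p = 0.0325, 0.0270, 0.0294 and 0.0117) and with the closest libraries summed (camera, adjusted p = 0.0129). ADIPOQ, the hormone adiponectin, fell by 6.51 (SE 0.62, edgeR, adjusted p = 4.67e-05). LEP, the hormone leptin, spanned 0.198 to 304 CPM in the tumours with a log2 change of 6.89 (SE 2.28, edgeR, adjusted p = 0.0310). Its call was lost by limma-voom (adjusted p = 0.624), with the closest libraries summed (edgeR, adjusted p = 0.131), by limma on the deposited log2 values (adjusted p = 0.115) and without muscle 1, 2 or 3 (edgeR, adjusted p = 0.105, 0.0833 and 0.102, with a log2 change of 7.91 without muscle 2).

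T and NK cell markers rose in 2 of 5 tested, 2 adjusted over the list alone, with 0 lower and a median of 2.27 (camera, adjusted p = 0.368). IL2RB, a receptor subunit for interleukin 2, rose by 3.86 (SE 0.90, edgeR, adjusted p = 0.00646), or by 3.08 without tumour 4. Of 4 neuron genes 1 rose and 1 fell, the same adjusted over the list alone, with a median of 1.53 above 0 but a test direction below that of other genes (camera, adjusted p = 0.948). GAD1 was 30.8-fold higher (counting interval 5.54 to 1218, from 1 read in muscle), with a fitted log2 change of 4.67 that was 4.06 without tumour 5 and 6.91 without muscle 2. CAMK2A, a kinase that muscle also expresses, fell by 8.44 (SE 0.38, edgeR, adjusted p = 1.67e-06). Of 6 glial genes 3 rose and 1 fell, the same adjusted over the list alone, with a median of 1.71 (camera, adjusted p = 0.776). MBP rose by 1.30 (SE 0.30, edgeR, adjusted p = 0.00598). Of 4 pigment cell genes 1 rose and 1 fell, the same adjusted over the list alone, with a median of 2.77, or 2.73 with genes at 0 set to their bound (camera, adjusted p = 0.948). PMEL was at least 9.97-fold higher with a total of 80 reads in tumours and 0 in muscle, a call lost by limma-voom (adjusted p = 0.0665) and with the closest libraries summed (edgeR, adjusted p = 0.0533). TYRP1 fell by 7.16 (SE 0.57, edgeR, adjusted p = 1.63e-05), with a log2 change of -7.82 without tumour 1. B cell, photoreceptor, red cell and epithelial lists had 1, 2, 2 and 1 tested members and were not tested as lists. The B cell gene was not called, and PRPH2 of photoreceptors fell by 3.25 (SE 0.63, edgeR, adjusted p = 0.00257). EPOR, the erythropoietin receptor, rose by 4.73 (SE 0.52, edgeR, adjusted p = 1.02e-04). HEMGN fell by 2.88 (SE 0.79, edgeR, adjusted p = 0.0139), a call lost without muscle 1 (edgeR, adjusted p = 0.0634) and with the closest libraries summed (edgeR, adjusted p = 0.0552). The epithelial cadherin CDH1 rose by 6.27 (SE 1.58, edgeR, adjusted p = 0.00939), 5.47 without tumour 5 and 7.49 without muscle 2, and was not called by limma-voom (adjusted p = 0.193).

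**Figure D3:**
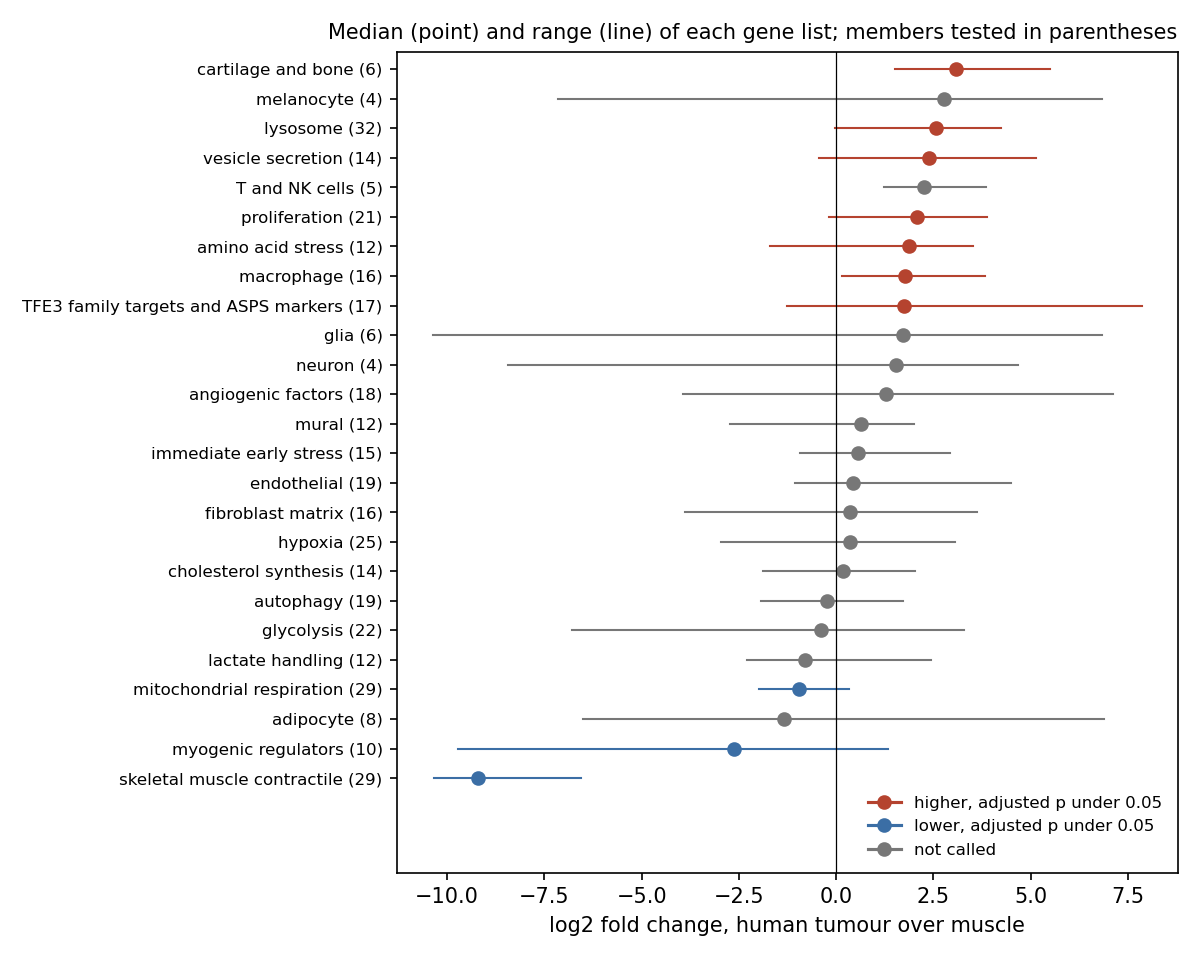
Each point is the median log2 fold change of tumour over muscle of the tested members of a human gene list, lines run from the lowest to the highest member, and colour marks lists called by camera at an adjusted p under 0.05. The contractile list lies lowest at a median of -9.19 and the lysosome list at 2.57, and fitted values of members with no read in one tissue depend on the prior count.

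The 8 largest rises past the expression minimum were of genes with 0 or 1 read in the 3 muscle libraries. LMAN1L and CPLX3 were at least 269-fold and 265-fold higher in tumours, with 2194 and 2169 reads in the 5 tumours and 0 in muscle. These neighbours on chromosome 15 had near-identical counts, with summed differences under 0.1 of their summed counts, so the split of reads between them is uncertain. By this measure TFE3 is close to its neighbour GRIPAP1, as are 490 tested genes to a neighbour. CYP4F22, a lipid-hydroxylating cytochrome P450, was at least 185-fold higher and TP73-AS3 at least 121-fold. LUZP4, GDF15, a secreted factor of the stress response, and KLK4, a secreted protease, were 1010-fold (counting interval 181 to 39884), 681-fold (122 to 26882) and 623-fold (112 to 24620) higher, and PKD1L1-AS1 was 737-fold higher (132 to 29120). Levels varied widely between tumours, 0.297 to 294 CPM for LUZP4, and without tumour 1 the fitted log2 changes of LUZP4, PKD1L1-AS1 and GDF15 were 6.03, 6.05 and 7.55 against 9.66, 9.21 and 9.09 with it. In leave-one-out, other fitted values that moved by over 1.5-fold were those of GDF15 without muscle 2 (11.35), LUZP4 and PKD1L1-AS1 without muscle 2 (11.92 and 11.46), TP73-AS3 without tumour 2 (9.82 against 10.44), and KLK4 without tumour 5 (8.26), muscle 2 (8.15) or muscle 3 (11.32), against 8.93 with all libraries. All 8 were called by edgeR, with adjusted p = 0.00139 to 0.0353, and by limma-voom none was, with adjusted p = 0.0552 to 0.335. By edgeR, the call of LMAN1L was lost without muscle 2 (adjusted p = 0.0504), that of CPLX3 without muscle 1, 2 or 3 (adjusted p = 0.0531, 0.0581 and 0.0531), and those of LUZP4 (adjusted p = 0.106, 0.130 and 0.105) and PKD1L1-AS1 (adjusted p = 0.0965, 0.121 and 0.0966) likewise. The call of LUZP4 was also lost by limma on the deposited log2 values (adjusted p = 0.0603). These 4 were lost as well with the closest libraries summed (edgeR, adjusted p = 0.0616 to 0.0888).

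The 8 largest falls were of muscle genes. AQP4, the water channel of the muscle fibre membrane, was 1822-fold lower in tumours (counting interval 504 to 15045, from 2 reads in tumours). LANCL1-AS1 was at least 304-fold lower, with 0 reads in tumours and 299 in muscle. CKM, the muscle creatine kinase, fell by 10.34 (SE 0.88, edgeR, adjusted p = 2.60e-05), from 15851 ± 8657 CPM in muscle (SD, n = 3) to 12.2 ± 9.38 CPM in tumours (SD, n = 5). ACTA1, skeletal muscle actin, fell by 10.07 (SE 0.96, edgeR, adjusted p = 4.69e-05). The myosin light chain MYL3 fell by 10.10 (SE 0.70, edgeR, adjusted p = 8.38e-06). SMTNL1, IDI2 and PPP1R1A had log2 changes of -10.09, -10.06 and -10.01 (edgeR, adjusted p = 3.24e-06, 1.04e-06 and 2.81e-06). Without tumour 1 the log2 changes of CKM, ACTA1, MYL3 and SMTNL1 were -10.93, -11.03, -10.77 and -10.90. The antisense genes TP73-AS3, PKD1L1-AS1 and LANCL1-AS1 cannot be told from their sense partners without strand. Counts are uncertain as well for genes that share exon bases with a neighbour, among them SLC16A1, SLC16A3, IDI2, PPP1R1A, ATP2A1, MEF2C, NDUFS1, NPC1, NPC2, PFKM, MPC2, ANKRD37, MYH11, TYMS, DDIT3, CD68, PMEL, TTN and NEB.

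The mouse comparison asks how tumours induced by the fusion differ from mouse muscle. As in human, muscle libraries were concentrated in few genes: the 50 genes most abundant in muscle took 56.9% ± 3.67 of muscle counts (SD, n = 3) and 3.38% ± 0.711 of tumour counts (SD, n = 5), and in human 67.4% ± 3.46 (SD, n = 3) and 5.87% ± 1.36 (SD, n = 5). By edgeR's quasi-likelihood test, 9958 of 14760 genes tested (67.5%) differed at an adjusted p under 0.05, 5408 higher and 4550 lower in tumours. Of these 4453 were at least 2-fold higher and 3230 at least 2-fold lower, and 1310 and 659 at least 16-fold. Every tumour lay on one side of every muscle sample for 9831 genes, of which 9400 were called, where chance separates 3.57% of genes. Mouse replicates spread less than human ones, with a biological coefficient of variation of 0.356 in mouse tumours and 0.179 in mouse muscle against 0.407 and 0.256 in human.

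The files pair mouse IDs with no names, so the largest changes are given by ID. ENSMUSG00000029697 and ENSMUSG00000046814 were at 32.7 ± 3.19 and 22.7 ± 8.08 CPM in tumours (SD, n = 5) with 0 reads in muscle, at least 196-fold and 137-fold higher (edgeR, adjusted p = 2.33e-07 and 7.76e-06). ENSMUSG00000046345 and ENSMUSG00000031204 were at 79.6 ± 5.09 and 50.4 ± 7.74 CPM in muscle (SD, n = 3) with 0 reads in tumours, at least 2308-fold and 1460-fold lower (edgeR, adjusted p = 3.78e-07 and 9.48e-07). For the 200 genes with the largest share of muscle counts, the share of tumour counts was divided by the share of muscle counts, without TMM scaling. The 5th percentile of this ratio lay at 0.0777% to 0.0879% in the 5 tumours. Which genes or gene groups the tumours of both species share is not analysed here.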

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

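No test in this part was chosen after the results were seen. In 67 sets of values over the 5 tumours of a species, the gap between the most distant library and its nearest neighbour was divided by the range of the group and set against Dixon's critical value of 0.71. Chance alone puts about 1 in 20 groups of values above it, and 7 of the 67 were above it.

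CTSK, the protease cathepsin K, was lowest in tumour 4 at a log2 CPM of 10.61, with the other 4 tumours at 11.10 to 11.17 (gap over range 0.860). LDHB was lowest in tumour 4 at 7.74, with the others at 8.51 to 8.79 (0.735). CYP4F22 was lowest in tumour 4 at -1.13, with the others at 4.78 to 5.95 (0.834). The myosin light chain MYL3 was highest in tumour 1 at 1.99, with the others at 0.07 to 0.56 (0.749). The mean of the amino acid response list was highest in tumour 1 at 4.91, with the others at 3.86 to 4.10 (0.771). The mean of the list of secreted vessel factors was lowest in tumour 4 at 4.21, with the others at 4.70 to 4.79 (0.843). The mean of the autophagy list was highest in tumour 1 at 5.96, with the others at 5.67 to 5.74 (0.769).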

How the results depend on the processing

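Summing the closest libraries, TMM without the 50 genes most abundant in muscle and limma on the deposited log2 values were chosen after the results were seen, and the cause was not tested for any change given here. The human comparison called 7794 genes, and 5095 to 8598 under the other settings. With the closest libraries summed it called 5095 genes, 2614 of them higher, and with a 2-fold minimum 2351 genes were lower. Leave-one-out gave 5715 (without muscle 3) to 8157 (without tumour 1). The mouse comparison called 9958 genes, and 7683 to 10537 under the other settings, with 8865 to 10085 in leave-one-out. All genes called both here and under another setting kept their direction. Of 111 called human genes named by the rule or chosen later, 89 were called under every setting. Over all settings, 58 named genes of both species lost or changed a call or moved by over 1.5-fold: 44 by limma on the deposited log2 values (3 calls lost), 32 in leave-one-out (35 calls lost over its fits), 24 by limma-voom (15 lost), 14 with the closest libraries summed (14 lost), 14 with the replicate block (2 lost) and 7 by DESeq2 (0 lost). Among the moves, limma on the deposited log2 values took ADIPOQ from -6.51 to -3.84 and TYRP1 from -7.16 to -4.42, and the replicate block took HEMGN from -2.88 to -4.66.

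The list test called 10 of 25 lists, 0 with an estimated correlation (camera, 4 at an unadjusted p under 0.05), 19 by fry and 9 to 11 in leave-one-out. List directions that reversed, with adjusted p: by fry, fibroblast 0.925, glia 0.0681 and pigment cell 0.0216; with the closest libraries summed (camera), fibroblast 0.871, hypoxia 0.969 and pigment cell 0.895; with the replicate block (camera), neuron 0.855. The replicate block also called the vessel factor (camera, adjusted p = 0.0404) and endothelial lists (camera, adjusted p = 0.0295) higher. In leave-one-out (camera), adjusted p ranged over 0.835 to 0.993 for cholesterol, 0.0935 to 0.943 for fibroblast, 0.603 to 0.993 for glia, 0.836 to 0.997 for hypoxia, 0.877 to 1.00 for pigment cell and 0.835 to 0.993 for neuron. The replicate block took MET to a log2 change of -0.073 (edgeR, adjusted p = 0.818). Same-number tumour and muscle correlated at -0.0233 to 0.0684 in human and -0.0820 to 0.00241 in mouse. Different numbers correlated at -0.0842 to 0.0533 in human and -0.157 to 0.149 in mouse. These values show no sign of pairing, but 3 same-number pairs per species across unlike tissues cannot exclude it. The species comparison, mouse gene lists, their alternatives and TMM without gene lists in mouse were not run, since mouse symbols were not used here, and the pseudocount alternatives apply to data without counts.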

Other observations

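The gene lists of this paragraph up to the mitochondrial genome, the counts of splits and the tests weighing technical explanations were chosen after the results were seen, and list p-values were adjusted over 5 such lists. Of 5 steroid synthesis genes 4 rose in human tumours, 4 adjusted over the list alone, with a median of 1.74, but the list was written because of its member CYP17A1, so its test is not given. CYP17A1, the steroid 17-hydroxylase, reached 3776 ± 2032 CPM in tumours (SD, n = 5) and 16.3 ± 7.75 CPM in muscle (SD, n = 3). Its log2 change of 7.86 is also the highest value in the list of TFE3 family targets and ASPS markers, which was written before the data were examined. CYP17A1 shares exon bases with its neighbour WBP1L, so its counts are uncertain. CYP11A1 rose by 2.86. Ribosomal protein genes fell in 40 of 74 and rose in 2, or 43 and 2 adjusted over the list alone, with a median of -0.71 (camera, adjusted p = 1.03e-06, and adjusted p = 0.416 with an estimated correlation). Over the scalings 36 to 44 of them were lower, but these scalings differ little, with a median log2 change of all genes of 0.09 to 0.18. The largest fall was that of RPL3L, at -9.67. Of 13 protein-coding genes of the mitochondrial genome 10 fell, 12 adjusted over the list alone, with a median of -1.38 (camera, adjusted p = 0.00111, and adjusted p = 0.416 with an estimated correlation). Before scaling, all genes of the mitochondrial genome together took 2.06% ± 0.960 of tumour counts (SD, n = 5) and 1.86% ± 0.423 of muscle counts (SD, n = 3). This share was not lower in tumours, so the fall of the mitochondrial genome rests on the scaling between libraries. The smaller median fall of ribosomal protein genes depends on the same scaling. The mean log2 CPM of the T and NK cell list was 4.28 in tumour 4 and 0.54 to 1.65 in the other tumours.

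If the 8 libraries of a species are separate samples, the splits argue against chance for its number of called genes, at 1 of 56, the smallest share possible. Every other split mixes tumour and muscle libraries in a group, which widens the spread there, so its low count is no measure of false calls. If the closest human libraries share a donor, the human splits are too few to argue against chance. Of the 56 splits of the 8 human libraries into 5 and 3, only 1, the real one, called as many as 7794 genes, and the highest other called 7. In mouse only 1 of 56, the real one, called as many as 9958, and the highest other called 0.

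Of 32 lysosomal genes 28 rose in human tumours, though the list was not called with an estimated correlation (camera, adjusted p = 0.257). Scaling of libraries in which TTN takes much of the counts is argued against as the source of a rise above other genes. The lysosome median lay 2.42 above that of all genes under the scaling with the smallest difference, and the highest of 10000 random lists reached 0.79. A scaling factor shifts all genes alike, so repeats over scalings (up to 2.44) were bound to give nearly the same difference and add no support. For macrophages as the only source, a comparison of medians did not decide. Without the shared member, the median of 31 lysosomal genes lay 0.898 above that of 15 macrophage markers. The permutation p was 0.115 and the difference ran from -0.61 to 1.78 between tumours. Levels per tumour did not decide either, since tumours 1 and 4 ran against this source as the only one and tumours 2, 3 and 5 ran with it. The mean log2 CPM of macrophage markers was highest in tumour 4 (6.27) and lowest in tumour 1 (4.93). For lysosomal genes it was lowest in tumour 4 (6.985) and highest in tumour 1 (7.76). Tumours 2, 3 and 5 lay between, at 5.07 to 5.61 and 7.27 to 7.38, in the same order in both lists. Activity of the fusion in tumour cells may also raise these genes, which was not tested.

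In mouse, the lowest shares of muscle transcripts were alike in the 5 tumours: over 200 muscle-abundant genes the 5th percentile differed by 1.13 times between the highest and lowest tumour, while the 25th percentile ran from 0.468% to 0.988% and the median from 14.0% to 19.7%. Carry-over of transcripts between libraries may explain this floor, but this was not decided. Per source count, tumour genes in muscle libraries stood at 1.45 times the rate of muscle genes in tumour libraries, within the tolerance of 2. In human the ratio was 1.63, also within that tolerance, but there the 5th percentile differed 8.75 times between tumours (0.107% to 0.933%), which 1 common rate of carry-over does not give. A ratio within the tolerance is therefore no support for carry-over. Remnants of muscle tissue or low transcription in the tumours stay open, since similar shares in 5 tumours decide neither.

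In human tumour 5, TTN and NEB stood at 0.816% and 1.21% of their muscle level, far above the median of 0.0387% of the other 27 contractile genes. Remnants of muscle tissue stay open as the source. In tumour 5, 16 of 173 muscle-abundant genes outside the contractile list lay more than 3 times below the smaller of these shares (2 to 7 genes in the other tumours). This count does not decide, since its cutoff is the share of TTN itself, which is part of the pattern. The bound of at least 5 genes was set after this value was seen and is also passed in tumours 2 and 3, which lack the pattern. Of the other contractile genes, PYGM stood at 1.44%. A bias towards long transcripts could not be decided, with a Spearman rho of 0.104 between share and gene model length over those 27 genes (permutation p = 0.606). No biological explanation was tested.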
